A study of Homo sapiens with 22 samples.

How the data were processed

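RNA-seq was analysed from 6 libraries of Kasumi-1 cells (DMSO, 250 nM JQ1 or 125 nM MS417, 1 h or 3 h), and ChIP-exo from 1 H3K27ac library of untreated cells. Per the labels' protocols, RNA was extracted with TRIzol, enriched for poly(A) and made into libraries with a TruSeq kit, and chromatin was fixed with formaldehyde before immunoprecipitation. PRO-seq samples, the primary leukaemia samples and the ChIP-exo input were not analysed here. Groups were taken from the treatment labels.

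Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.32, Bowtie2 2.2.4, TopHat2 2.0.10 and MACS2 2.0.10 were used in the series, with the build hg19, without saying which tool made which file. The authors deposited RNA values as RPKM per RefSeq transcript, per the file headers, although the files are titled as normalized counts. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Each of the 11774 transcripts listed reached at least 1.004 RPKM in 1 library or more, so genes below that in every library are not listed. RPKM fixes the total per library, so a change of all transcripts together could not be seen.

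Peaks were called by the authors with MACS 2.0.10 on 1 library against the input, per the file headers, with a q cutoff of 0.05, an extension of 200 bp and 1 tag kept per position. The deposited peak list gives the pileup signal at the summit after scaling to the smaller library, the fold enrichment ratio over local background, and −log10 p and q values, per the file headers. Per the file headers, 24.5 M of 45.3 M H3K27ac tags were kept (redundant rate 0.46) and 76.8 M of 87.8 M input tags (0.12). The peak length deposited by the authors is in base pairs. Positions are given as in the list.

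Transcript identifiers were matched to symbols through the RefSeq gene table of assembly GRCh38.p14, used for names only. Of 11774 transcripts 11455 had a symbol and 319 did not, and these kept their identifiers. Where several transcripts shared a symbol, the one with the highest mean was kept (63 left out), which gave 11711 genes.

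Depth was recovered from the values. Short hairpin RNA genes of known length gave the number of reads per library that RPKM had been scaled to, refined on intronless genes. With these totals 11773 of 11774 transcripts (99.99%) gave whole reads in all 6 libraries, within 0.03 reads at low counts and at most 0.25 reads. The totals were 25.4 M reads (DMSO 1 h), 27.2 M reads (JQ1 1 h), 23.8 M reads (MS417 1 h), 24.2 M reads (DMSO 3 h), 26.3 M reads (JQ1 3 h) and 26.2 M reads (MS417 3 h). A single length fitted for 0.6% of transcripts, since multiples of a fitting length also fit, and the smallest was used. For abundant transcripts many lengths fit, so whole reads say little there, and counting intervals were computed only up to 25000 reads. Of 47 hairpin RNA genes 35 came out at their annotated length, which is no independent check, since hairpin genes gave the first totals. The 95% counting intervals cover counting error only.

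Values were compared as log2(RPKM + 0.5) for the 11225 genes with a mean of at least 1 RPKM over the libraries. Fold changes are on this scale, which understates the change of low genes. Single pairs of libraries have no replicate check, so genes at least 2-fold apart were counted with no p-value. The design fixed before the data were examined was limma 3.58.1 in R 4.3.3 with additive terms for treatment and time over all 6 libraries, which leaves 2 residual degrees of freedom. These hold the change of the response between 1 h and 3 h together with library noise, so genes whose response differs between the times are hard to call. A second limma fit was chosen after the data were seen. It treats JQ1 and MS417 as 2 samples of inhibitor treatment at each time, gives the response at 1 h, at 3 h and the difference between them, and takes its spread from the JQ1 to MS417 differences. Calls are at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p in the text are from limma. It moderates the spread of each gene toward a value estimated from all genes, so SEs, intervals and p-values also rest on other genes.

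Both fits were tested on simulated reads for 11225 genes with a dispersion of 0.005. The additive fit recovered 89.6% of genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold for inhibitors against DMSO, with 21 unchanged genes among 214 calls. For 3 h against 1 h it recovered 92.5% of genes changed 1.5-fold, with 10 unchanged genes among 205 calls. The fit by time recovered 49.3% of genes changed 1.5-fold and 97% of those changed 2-fold at 3 h, with 19 unchanged genes among 183 calls. For the difference between times it recovered 11.9% and 70.1%, with 22 unchanged genes among 143 calls. The simulated changes were alike at both times in the additive case, which real responses need not be. All simulated libraries were drawn independently with the same dispersion, so DMSO libraries varied like the others. In the data the spread of the fit by time leaves out variation between DMSO cultures. The share of false calls simulated for that fit therefore does not carry over to its calls in the data.

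The named genes follow a rule fixed before the data were examined: the 8 highest and 8 lowest differences of each pair of an inhibitor with DMSO, up to 10 per direction that passed over both times with the same sign in all 4 pairs, the 5 highest and 5 lowest for MS417 against JQ1 and for 3 h against 1 h, KIT, MYC, BCL2, CCND2, CDK6, RUNX1, RUNX1T1, HEXIM1 and 1 more gene that is not reported here, and of each gene list up to 4 members with the largest difference over both times and any that passed there, and the 10 largest H3K27ac regions. Hypoxia genes outside this rule were chosen after their values were seen. RNA genes under 200 bases were to be counted and could be left unnamed. Such short RNA genes were told by the start of their names, as for microRNA and small nucleolar RNA genes, and not by measured length. They were mostly left unnamed. The 19 gene lists were fixed at the same point. A list's median was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Older histone symbols that fit several genes were left out. Lists of heat shock genes and of hypoxia genes were added after the data were seen.

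Comparisons that share a DMSO library were set beside 100 simulated sets of unchanged groups. Peaks were joined over gaps of up to 10000 bp, and regions ranked by summed peak length. The planned share of peaks at transcription starts, and the expression response by H3K27ac class, need gene positions in hg19, which were not used here. Alternatives were pseudocounts of 0.1 and 2, no filter, a mean of at least 5 RPKM, rescaling by the median of ratios, moderation with trend and robust settings, both inhibitors as 1 level, leaving out each library, and limma with voom weights on the whole reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.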

Results

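Messenger RNA and an active chromatin mark were profiled in Kasumi-1, an acute myeloid leukaemia cell line that carries the t(8;21) translocation and its RUNX1-RUNX1T1 fusion. Cells received the solvent DMSO, 250 nM JQ1 or 125 nM MS417, both inhibitors of BET bromodomain proteins, for 1 h or 3 h. Polyadenylated RNA gave 1 RNA-seq library for each of the 3 treatments at each of the 2 times, 6 libraries in all. Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by ChIP-exo in 1 untreated library. Files of 7 of the 22 samples were analysed; 14 samples of nascent RNA (PRO-seq), 12 from the cell line and 2 from primary leukaemia cells, and the ChIP-exo input were not analysed here. The RPKM values had been scaled to between 23.8 M reads (MS417 1 h) and 27.2 M reads (JQ1 1 h), as worked out from the steps between low values. Of the 11774 transcripts listed, 11225 genes with a mean of at least 1 RPKM were compared.

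The first question was which transcripts the BET inhibitors changed at both times. Over 1 h and 3 h together, 8 genes rose and 16 fell against DMSO out of 11225 tested. The largest fall was that of MYC, the growth-promoting transcription factor, by 2.69 on the log2 scale (SE 0.17, adjusted p 0.0459), from 323 RPKM in DMSO at 1 h to 39.8 with JQ1 and 38.2 with MS417. The BMP antagonist NOG fell by 1.68 (SE 0.13) and its ligand BMP4 fell by 1.36 (SE 0.09). The pseudokinase gene TRIB1 (-1.43), CD200 (-1.39), a cell surface glycoprotein, and SPRY1 (-1.31), an antagonist of receptor tyrosine kinase signalling, also fell. So did the receptor genes GPR132 (-1.29) and GPR84 (-1.29), the starch-binding protein gene STBD1 (-1.28) and RHOH (-1.19), a GTPase gene of blood cells.

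The 8 genes that rose over both times were LSMEM1 (2.12, SE 0.14), the GTPase gene RND1 (2.10, SE 0.16), the cell cycle regulator SERTAD1 (2.09, SE 0.10), RGS2 (2.01, SE 0.12), a regulator of G-protein signalling, the immediate early gene EGR1 (1.38, SE 0.10), NFIL3 (1.18), TIPARP (1.08) and BAMBI (0.99). Each had an adjusted p of 0.0459 in limma and the same sign in all 4 pairs of an inhibitor library with its DMSO library. LSMEM1 rested on 7 reads in DMSO at 1 h against 79 with JQ1. SERTAD1 rested on 77 reads against 343, and EGR1 on 83 against 357. JQ1 alone and MS417 alone passed for 0 genes in limma over both times, and for 0 with voom weights on whole reads; at an unadjusted p under 0.05 there were 693 rising and 956 falling for JQ1, and 712 and 1089 for MS417. All calls were lost without any 1 of the 4 inhibitor libraries, in a fit with fewer residual degrees of freedom. Leaving out DMSO 1 h reduces the contrast to the response at 3 h, and leaving out DMSO 3 h to that at 1 h. Leaving out a DMSO library therefore does not test the result over both times. With a mean of at least 5 RPKM 0 genes passed, 8 fell with a pseudocount of 0.1, 5 rose with a pseudocount of 2, and with both inhibitors as 1 treatment level 162 rose and 244 fell.

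**Figure D1:**
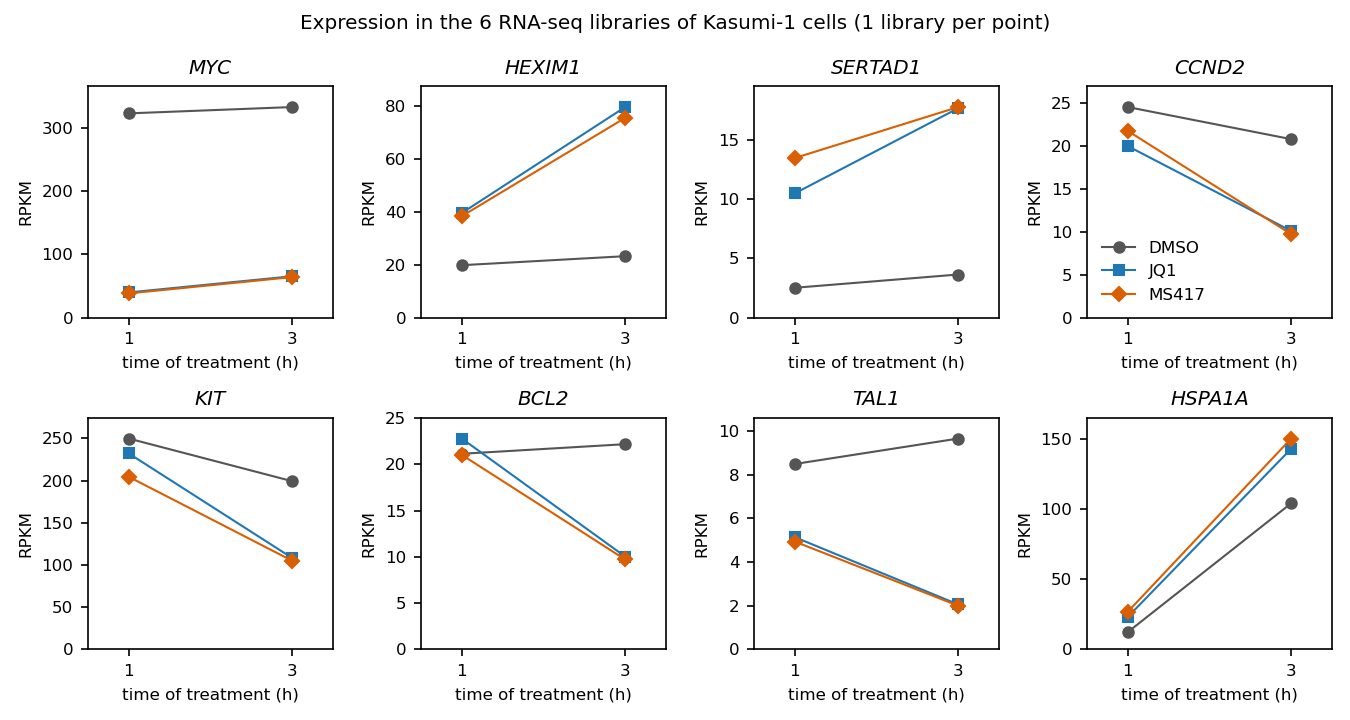
RPKM (vertical axes, from 0) of 8 genes in the 6 libraries at 1 h and 3 h of treatment (horizontal axes), 1 library per point with no error bar, and lines joining libraries of one treatment. MYC lay at 323 and 333 RPKM in the DMSO libraries and between 38.2 and 65.3 RPKM in the 4 inhibitor libraries.

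The response at 1 h was small in number and large for a few genes. MYC was 8.19-fold lower (log2 -3.03, SE 0.06), with a 95% interval from -3.19 to -2.88. SERTAD1 (2.04, SE 0.14), LSMEM1 (1.86, SE 0.07), RND1 (1.82, SE 0.12), RGS2 (1.81, SE 0.06) and EGR1 (1.54, SE 0.09) rose. HEXIM1, which encodes an inhibitor of the elongation kinase P-TEFb, rose 1.94-fold (0.96, SE 0.07), from 19.8 RPKM to 39.5 with JQ1 and 38.3 with MS417. TENT5A (-1.80, SE 0.12), BMP4 (-1.49), TRIB1 (-1.46), NOG (-1.45), TASL (-1.40) and the AP-1 gene FOSL2 (-1.16) fell, as did GATA2 (-1.03, SE 0.09) and TAL1 (-0.70, SE 0.06), transcription factors of early blood cells. The receptor gene KIT (-0.20, SE 0.09), BCL2 (0.05, SE 0.07), CCND2 (-0.23, SE 0.08) and CDK6 (-0.01, SE 0.09) did not pass at 1 h, with adjusted p of 0.3, 0.74, 0.17 and 0.98. Their 95% intervals, not adjusted for the number of genes, ran from -0.43 to 0.03 for KIT and from -0.14 to 0.23 for BCL2. They ran from -0.42 to -0.04 for CCND2 and from -0.23 to 0.22 for CDK6. Changes within these ranges at 1 h are not excluded.

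In total 183 genes rose and 362 fell at 1 h, of which 13 and 28 by at least 2-fold. This fit took JQ1 and MS417 as 2 samples of inhibitor treatment at each time and was chosen after the data were seen. Its spread is the difference between the inhibitors pooled over both times, with 2 residual degrees of freedom per gene, moderated toward the spread of all genes. The single DMSO library of each time is assumed to vary alike. The inhibitor libraries differed more at 1 h (chi-square of the reads 4.74 per gene) than at 3 h (1.38), so SEs at 1 h may be too small. Variation between DMSO cultures is not part of this spread, so the number of calls at 1 h may be too high. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these libraries. Without MS417 1 h, 0 genes rose and 1 fell, which was MYC; without JQ1 1 h, 31 rose and 74 fell; without JQ1 3 h or MS417 3 h, 72 rose and 100 fell. With a pseudocount of 2, 570 fell, and with voom weights on whole reads, 650. As single pairs, with no replicate check and no test, JQ1 differed from DMSO by at least 2-fold at 17 genes upward and 29 downward, and MS417 at 19 and 44. With a pseudocount of 2 these were 5 and 10 for JQ1 and 6 and 17 for MS417, and with a pseudocount of 0.1 they were 39 and 44 for JQ1 and 46 upward for MS417. With the pseudocount of 0.5, short RNA genes, told by their names, made up 7 and 7 for JQ1 and 4 and 7 for MS417. Among them, the microRNA gene MIR223 had 36 reads in DMSO, 11 with JQ1 and 14 with MS417.

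At 3 h the same fit called 2764 rising and 2794 falling genes, of which 179 and 317 by at least 2-fold. These calls set single DMSO libraries against the spread between JQ1 and MS417, whose 3 h libraries differed by a chi-square of 1.38 per gene, close to counting noise, while the DMSO libraries of 1 h and 3 h differed by 11.5. Variation between DMSO cultures is not part of that spread, so the number of calls may be too high, here, at 1 h and for the change between the times. The largest rises were those of ZCCHC24 (2.52, SE 0.13), IRF7 (2.49, SE 0.10), a transcription factor of the interferon response, RND1 (2.38), LSMEM1 (2.37), CEMIP2 (2.35), TESK2 (2.32), FAM222A (2.30) and IQCN (2.28). IRF7 went from 1.49 RPKM in DMSO to 9.88 with JQ1 and 11.5 with MS417. The largest falls were those of FJX1 (-3.07, SE 0.06), TFAP4 (-2.74, SE 0.09), a transcription factor gene known as a MYC target, ANKRD22 (-2.44), MYC (-2.35, SE 0.06), PLD6 (-2.33), HOXD13 (-2.27), the clock gene NR1D1 (-2.22), KANK1 (-2.19) and SAMD10 (-2.15). FJX1 went from 21.7 RPKM in DMSO to 2.18 and 2.12. MIR223 fell by 2.01 (SE 0.40, adjusted p 0.0106 in limma) on 32 reads in DMSO against 11 and 5. The RNA was enriched for poly(A), and whether these reads come from the mature microRNA was not tested.

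Of the 8 genes chosen beforehand for their role in this leukaemia or as BET targets and reported here, 5 fell at 3 h and 1 rose. KIT fell 1.87-fold (-0.90, SE 0.09, adjusted p 0.0013), from 199 RPKM to 108 with JQ1 and 105 with MS417. BCL2, which restrains apoptosis, fell 2.19-fold (-1.13, SE 0.07, adjusted p 0.00044), from 22.2 RPKM to 10.0 and 9.71. CCND2, which encodes cyclin D2, fell 2.05-fold (-1.03, SE 0.08), and its kinase gene CDK6 fell 1.37-fold (-0.46, SE 0.09, adjusted p 0.0097). HEXIM1 rose 3.29-fold (1.72, SE 0.07), to 79.5 RPKM with JQ1 and 75.4 with MS417. RUNX1 (-0.13, SE 0.09, adjusted p 0.27) and RUNX1T1 (0.12, SE 0.09, adjusted p 0.31) did not pass. Their 95% intervals ran from -0.34 to 0.09 and from -0.10 to 0.34. The values of RUNX1 and RUNX1T1 are per listed transcript, and reads of the fusion were not separated from those of the normal genes.

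As single pairs at 3 h, 192 genes were higher and 319 lower by at least 2-fold with JQ1, and 184 and 322 with MS417. With a pseudocount of 2 they were 58 and 152 with JQ1 and 55 and 153 with MS417, and with a mean of at least 5 RPKM 69 and 187, and 65 and 191. Leaving out JQ1 3 h gave 1689 rising and 1805 falling genes in the fit, and leaving out MS417 3 h gave 1643 and 1805. Since nearly as many genes passed as did not, membership counts of a list at 3 h are given with the percentile of the list's median among 10000 random lists matched on expression.

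The change of the response between the times was computed in the same fit, as the response at 3 h minus that at 1 h. It was higher at 3 h for 1398 genes and lower for 1303, of which 75 and 148 by at least 2-fold. TESK2 (2.33, SE 0.12), CEMIP2 (2.17), ZCCHC24 (2.16) and IRF7 (1.83) were among the former, and TFAP4 (-2.17, SE 0.13), ANKRD22 (-1.98) and FJX1 (-1.96) among the latter, each with an adjusted p between 0.00559 and 0.00648. BCL2 (-1.18, SE 0.10, adjusted p 0.0066), CCND2 (-0.80, SE 0.11) and KIT (-0.70, SE 0.13, adjusted p 0.02) gained a fall. MYC moved the other way: its difference from DMSO shrank by 0.68 (SE 0.09, adjusted p 0.011), from 39.8 to 65.3 RPKM in the JQ1 libraries and from 38.2 to 64.0 RPKM in the MS417 libraries. TENT5A (0.67, SE 0.16) and DUSP4 (0.67, SE 0.09) did likewise. For SERTAD1 the change between times was 0.10 (SE 0.20, adjusted p 0.742) and for GATA2 -0.06 (SE 0.13, adjusted p 0.785). Without JQ1 3 h the counts were 297 and 402, and without MS417 3 h they were 243 and 344.

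**Figure D2:**
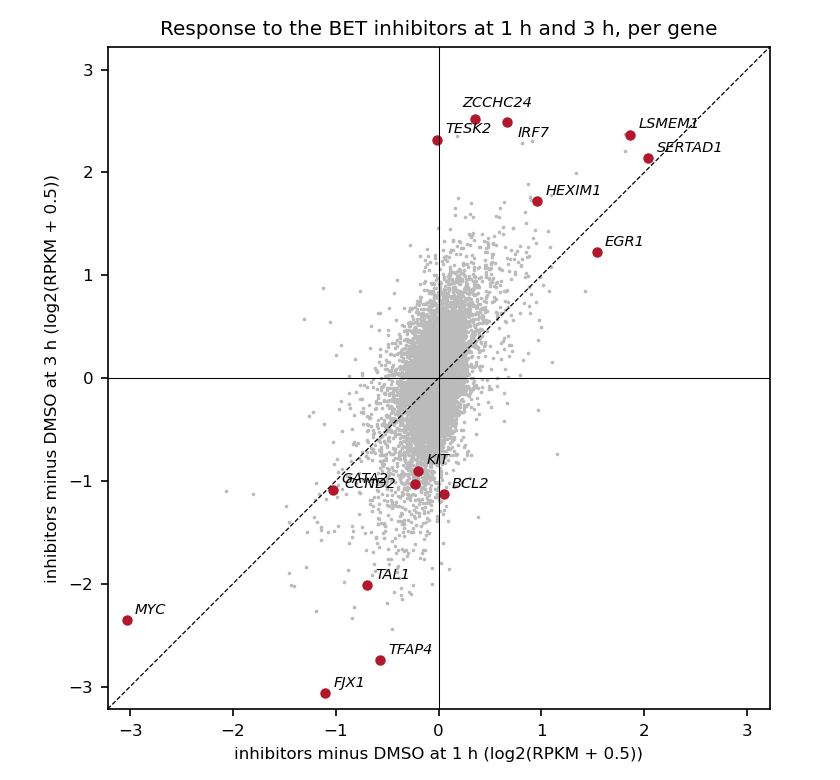
Difference of the mean of both inhibitors from DMSO on the log2(RPKM + 0.5) scale at 1 h (horizontal axis) and 3 h (vertical axis), 1 point per gene for 11225 genes, with 15 genes in red and the line of equal response dashed. MYC lies at -3.03 and -2.35, above the line, while BCL2 lies at 0.05 and -1.13.

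Of the genes called at 1 h, 167 of the 183 that rose also rose at 3 h and 281 of the 362 that fell also fell; independent calls would share 45.1 and 90.1. Of the others, 3 of the rising and 11 of the falling genes passed in the opposite direction at 3 h. Both sets share the spread estimate, which adds to such an overlap.

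Lists of genes fixed beforehand were examined next. Genes known from other cells to rise with BET inhibitors had a median of 0.60 at 1 h, with 3 of 6 measured members rising, and 1.73 at 3 h, with 6 of 6 rising; adjusted over the list alone the counts were 3 and 6. SERTAD1, ZCCHC24, HEXIM1 and the histone gene H2BC5 (1.51, SE 0.07 at 3 h) led it by the difference over both times. SERPINI1 rose by 1.75 at 3 h. Genes known to fall had a median of -0.85 at 3 h, with 7 of 8 falling, also 7 adjusted over the list alone, against 3 of 8 at 1 h. MYC, MYCN (-0.62, SE 0.09) and FOSL1 (-1.84, SE 0.19), an AP-1 factor, were among them. Both medians at 3 h lay at the ends of the random lists, at percentiles 100 and 0.

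Haematopoietic transcription factors that passed the test all fell. At 1 h 7 of 30 fell and 0 rose (median -0.23), 15 adjusted over the list alone, and at 3 h 22 fell and 0 rose (median -0.45), 23 adjusted over the list alone; both medians were at percentile 0. TAL1 fell by 2.01 (SE 0.06) at 3 h, from 9.67 RPKM to 2.05 with JQ1 and 1.99 with MS417. CEBPE (-1.60, SE 0.06), a granulocyte factor, ZEB2 (-1.51, SE 0.13) and GATA2 (-1.08, SE 0.09) also fell. Among growth factor receptors and their signalling genes 4 rose and 10 fell of 31 at 3 h (4 and 9 adjusted over the list alone), with a median of -0.07 at percentile 15.5, against 0 and 3 at 1 h (0 and 5). SPRY1 (-1.48, SE 0.07) and KIT fell and DUSP5 (0.65, SE 0.13) rose; DUSP4 was at -0.13 (SE 0.06, adjusted p 0.133) after a fall by 0.81 at 1 h.

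MYC targets and ribosome biogenesis genes fell mostly at 3 h. At 1 h 1 of 27 fell (median -0.06, percentile 0.03), and at 3 h 24 of 27 fell and 0 rose (median -0.39, percentile 0), also 24 adjusted over the list alone. RRS1, an assembly factor of the large ribosomal subunit, fell by 0.46 at 1 h and by 1.37 at 3 h (SE 0.06). NOP16 (-1.40, SE 0.07), POLR1B (-1.32, SE 0.08), which encodes a subunit of RNA polymerase I, and WDR43 (-1.06, SE 0.07) fell at 3 h. The change between the times passed for 16 of the 27, all downward.

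Cell cycle regulators leaned downward at 1 h, with 22 of 26 below 0 (median -0.10, percentile 0.06), 3 rising and 6 falling, also adjusted over the list alone. At 3 h 11 rose and 7 fell (11 and 9 adjusted over the list alone; median 0.01, percentile 58.6), and the median change between the times was 0.16 (percentile 99.9). CDKN2D, a CDK inhibitor gene, rose by 1.19 (SE 0.10) and GADD45A by 0.76 (SE 0.06), while CCND1 (-1.16, SE 0.07) and E2F2 (-0.63, SE 0.06) fell. Of 18 apoptosis regulators 4 rose and 6 fell at 3 h and 0 passed at 1 h, with the same counts adjusted over the list alone and a median of -0.03 (percentile 37.7). The survival gene MCL1 rose by 0.73 (SE 0.06) at 3 h, from 51.6 RPKM to 86.9 and 84.5, whereas its relatives BCL2 and BCL2L1 (-0.54, SE 0.06) and the death receptor gene FAS (-1.07, SE 0.10) fell. Of 18 p53 targets 9 rose and 5 fell, also adjusted over the list alone (median 0.26, percentile 98.5); SESN2 rose by 1.42 (SE 0.08) and AEN fell by 1.55 (SE 0.06).

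Of 28 genes for transcription elongation and BET proteins 12 rose and 3 fell at 3 h (13 and 3 adjusted over the list alone; median 0.05, percentile 84.1), against 1 and 1 at 1 h (2 and 1 adjusted over the list alone). HEXIM1, the elongation factor gene ELL2 (1.40, SE 0.06) and POLR2A (0.93, SE 0.08), which encodes the largest subunit of RNA polymerase II, rose. HEXIM2 fell by 0.51 (SE 0.07). POLR2A is also one of the 18 reference genes, of which 4 rose and 0 fell at 3 h (2 and 0 adjusted over the list alone; median 0.14, percentile 99.7); GAPDH was at 0.19 (SE 0.07, adjusted p 0.0794).

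Immediate early genes had a median of 0.40 at 3 h (percentile 99.9), with 8 rising and 4 falling of 15 (9 and 4 adjusted over the list alone), and 4 and 3 at 1 h (7 and 5 adjusted over the list alone; median 0.12). The median change of the response between the times was 0.12 (percentile 78.2), and in DMSO alone the list was lower at 3 h than at 1 h, with a median of -0.32 and 14 of 15 genes below 0. EGR1 rose by 1.23 (SE 0.09) at 3 h, from 0.526 RPKM to 2.02 and 1.79, and FOSL1, FOSL2 (-1.13, SE 0.17) and the phosphatase gene DUSP2 (-1.54, SE 0.07) fell. Inflammatory cytokines and NF-kB targets fell at 4 of 10 genes at 1 h and 6 of 10 at 3 h, with 0 rising, 6 at either time adjusted over the list alone (medians -0.45 and -0.44, percentiles 0 and 0.2). CXCL8 (-1.68, SE 0.19), ICAM1 (-0.62, SE 0.07), NFKBIE (-0.54, SE 0.09) and IRF1 (-0.34, SE 0.06) were among them. Of 18 interferon-stimulated genes 6 rose and 5 fell at 3 h (7 and 5 adjusted over the list alone; median 0.19, percentile 89.4). IRF7 and STAT2 (0.70, SE 0.06) rose, IFI44 (-0.51, SE 0.08) fell and OAS1 was at -0.39 (SE 0.15, adjusted p 0.0759).

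Myeloid granule and differentiation genes passed at 0 of 15 genes at 1 h and fell at 3 at 3 h, with 0 rising, also 3 adjusted over the list alone (median -0.04, percentile 19.1). The 3 were the Fc receptor gene FCGR1A (-1.61, SE 0.07), the myeloid surface marker CD33 (-1.21, SE 0.06) and the progenitor marker CD34 (-0.68, SE 0.06). AZU1, a granule protein gene, was at 0.18 (SE 0.08, adjusted p 0.125). Among markers of other lineages, 2 of 3 erythroid and megakaryocyte genes fell, KLF1 (-1.14, SE 0.07) and EPOR (-0.47, SE 0.11), and 2 of 7 lymphoid genes, CD247 (-2.08, SE 0.09) and CD79B (-0.95, SE 0.09), with 0 rising and the same counts adjusted over the list alone. The medians of these lists were -0.47 (percentile 6.43) and -0.11 (percentile 21). Of 5 measured replication-dependent histone genes 3 rose (median 0.41, percentile 94.4), H2BC5, H2AC18 (1.07, SE 0.20) and H2BC12 (0.41, SE 0.08); adjusted over the list alone 3 rose and 1 fell. Such transcripts mostly lack a poly(A) tail and are near-identical, so their values from polyadenylated RNA are uncertain.

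Cholesterol synthesis and uptake genes rose at 9 and fell at 2 of 18 genes at 3 h, also adjusted over the list alone (median 0.14, percentile 97.6). STARD4 (0.92, SE 0.11), SC5D (0.53, SE 0.06), IDI1 (0.52, SE 0.06) and MVK (0.52, SE 0.10) rose. Heat shock and unfolded protein response genes rose at 11 and fell at 2 of 18 genes at 3 h (12 and 2 adjusted over the list alone; median 0.24, percentile 100), and at 3 and 2 at 1 h (4 and 2 adjusted over the list alone; median 0.08, percentile 97.8). HSPA1B (0.57, SE 0.09) and HSPA1A (0.49, SE 0.10) rose at 3 h by less than at 1 h (0.98 and 1.00), although the change between the times did not pass (-0.41, adjusted p 0.0729, and -0.51, adjusted p 0.0556), and TRIB3 (-1.16, SE 0.07) and XBP1 (-0.85, SE 0.06) fell at 3 h, and by 0.63 and 0.54 at 1 h. Heat shock genes were also higher at 3 h than at 1 h in DMSO alone, with HSPA1A at 12.2 and 104 RPKM.

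**Figure D3:**
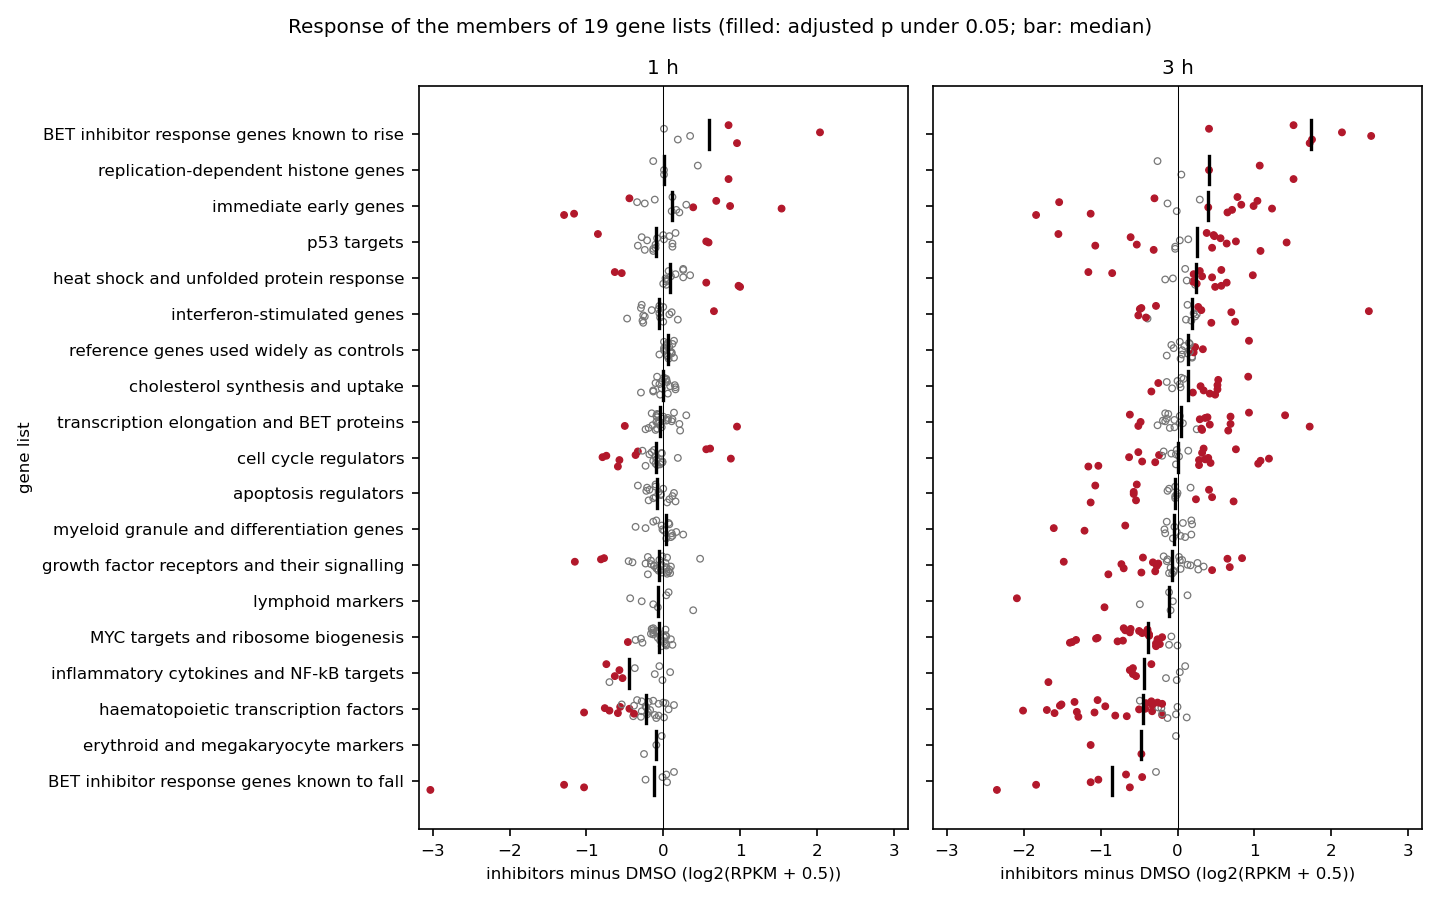
Difference of the mean of both inhibitors from DMSO on the log2(RPKM + 0.5) scale (horizontal axes) for the members of 19 gene lists (vertical axis) at 1 h and 3 h, 1 point per gene, filled red where the adjusted p was under 0.05, with black bars at the medians. The median of the MYC targets moves from -0.06 to -0.39 and that of the haematopoietic transcription factors from -0.23 to -0.45.

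The inhibitors were compared with each other at the doses used, which differ (250 nM JQ1 and 125 nM MS417). Over both times 0 genes passed for MS417 against JQ1 in limma, with 35 higher and 31 lower at an unadjusted p under 0.05 and a smallest adjusted p of 1; with voom weights on whole reads 0 passed as well. The 95% intervals of the difference (MS417 minus JQ1) ran from -0.57 to 0.48 for MYC, from -0.66 to 0.43 for KIT, from -0.94 to 0.78 for BCL2 and from -0.64 to 0.52 for HEXIM1. They ran from -0.58 to 0.65 for CCND2 and from -0.49 to 0.30 for CDK6. Differences within these ranges are not excluded. The spread of this fit also holds the change of the inhibitor response between 1 h and 3 h, which widens the intervals. The absence of calls therefore does not show that the inhibitors acted alike. By single pairs, MYC differed by -0.06 at 1 h and -0.03 at 3 h, and KIT by -0.18 and -0.04.

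At least 2-fold between the inhibitors were 6 genes upward and 7 downward at 1 h, of which 5 and 7 were short RNA genes, and 0 and 4 at 3 h, all 4 short RNA genes. With a pseudocount of 2 there were 1 and 2 at 1 h and 0 downward at 3 h, and with a pseudocount of 0.1 there were 11 downward at 1 h and 2 and 9 at 3 h. These rest on few reads: the small nucleolar RNA gene SNORD89 had 4 reads with JQ1 and 12 with MS417 at 1 h. Apart from the short RNA genes, the central 95% of 11139 genes lay between -0.30 and 0.22 at 1 h and between -0.21 and 0.20 at 3 h. Over 10994 genes the chi-square of the whole reads per gene was 4.74 between JQ1 and MS417 at 1 h and 1.38 at 3 h, where counting noise alone gives about 1. Against DMSO it was 10.3 for JQ1 and 14.5 for MS417 at 1 h, and 55.7 and 56.4 at 3 h. Between the DMSO libraries of 1 h and 3 h it was 11.5, in the range of the inhibitor pairs at 1 h.

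Across genes the JQ1 and MS417 differences from DMSO correlated at 0.799 (Pearson) at 1 h and 0.972 at 3 h, with covariances of 0.0411 and 0.206. Both use the same DMSO library, and simulated unchanged groups gave 0.501 and a covariance of 0.0191 with the spread of the additive fit. With the spread between JQ1 and MS417 the simulated covariance was 0.0054. Pairs that share no library correlated at 0.536 (JQ1 1 h with MS417 3 h), 0.474 (MS417 1 h with JQ1 3 h), 0.55 (JQ1 at both times) and 0.467 (MS417 at both times). Genes are not independent replicates, so no p is given. At 3 h the genes at least 2-fold apart shared 155 upward and 278 downward between the inhibitors, where independent lists would share 3.15 and 9.15; at 1 h they shared 11 and 25, against 0.0288 and 0.114. Part of this excess may come from the shared DMSO library, which could not be split.

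**Figure D4:**
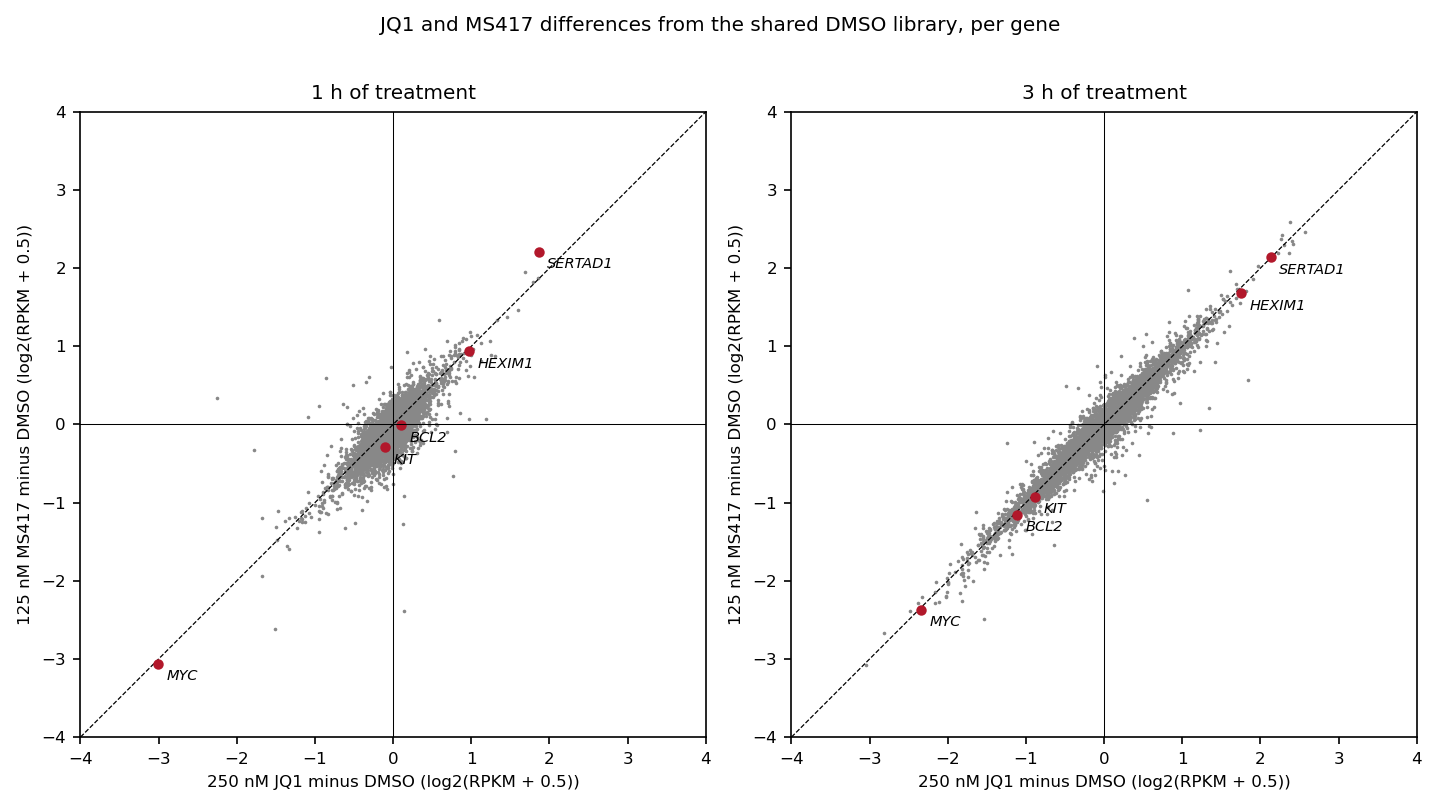
Difference from DMSO on the log2(RPKM + 0.5) scale with 250 nM JQ1 (horizontal axes) and 125 nM MS417 (vertical axes) at 1 h and 3 h, 1 point per gene for 11225 genes, with 5 genes in red and the line of equal difference dashed. The points lie closer to the line at 3 h (r = 0.972) than at 1 h (r = 0.799), and both axes share the DMSO library of that time.

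Time in culture was examined across the 3 treatments. Heat shock genes were the ones that rose from 1 h to 3 h: HSPA1A by 2.71 (SE 0.13), HSPA1B by 2.46 (SE 0.12), HSPA1L by 1.74 (SE 0.09), each with an adjusted p of 0.0351, and DNAJB1, a co-chaperone gene, making 4 genes rising and 0 falling. At an unadjusted p under 0.05 there were 2174 rising and 1322 falling; with voom weights 8 rose and 2 fell, with a pseudocount of 0.1 none rose (0 genes), and with a pseudocount of 2, 8 rose and 3 fell. HSPA1A and HSPA1B are near-identical copies whose reads may be split between them. TOX (-1.93, SE 0.34, adjusted p 0.0974) and RASSF5 (-1.63, SE 0.20, adjusted p 0.0974) were among the 5 lowest values and did not pass. In the DMSO libraries alone 14 genes were at least 2-fold higher and 10 lower at 3 h, of which 6 and 5 were short RNA genes; with a pseudocount of 2 there were 7 and 1, and with a pseudocount of 0.1 22 were lower. HSPA1A (3.05), HSPA1B (2.73), HSPA1L (1.6) and DNAJB1 (1.35) were the highest of the longer genes, and MIR210HG (-1.56) and the glycolysis regulator PFKFB4 (-1.25) the lowest.

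In untreated cells 54170 H3K27ac peaks, as called by the authors, covered 68.2 Mb of the hg19 build. Their median length was 730 bp (quartiles 357 and 1657 bp) and the authors' fold enrichment over local background had a median of 5.84, with 3.13 and 23.4 at the 10th and 90th percentiles. Peaks of at least 2000 bp were 10436 (19.3%) and held 53.9% of the peak length. Their median fold was 21.2, against 3.78 for peaks shorter than 500 bp. Joined over gaps of up to 10 kb, the peaks formed 23883 regions, 11902 of them single peaks, and the 300 largest by summed peak length held 11.9% of it. The largest lay on chromosome 11 from 122525741 to 122634768, with 35 peaks summing to 82.7 kb. Next came chromosome 5 from 134692774 to 134802538 (71.4 kb), chromosome 8 from 130639960 to 130709132 (60.5 kb), chromosome 12 from 11869476 to 11970201 (59.8 kb) and chromosome 12 from 118737811 to 118815905 (59.3 kb). The others of the 10 largest lay on chromosome 13 from 41534444 to 41595075 (57.4 kb), chromosome 8 from 130546512 to 130609398 (55.5 kb), chromosome 11 from 128515478 to 128598346 (53.8 kb), chromosome 9 from 80456984 to 80576943 (53.1 kb) and chromosome 2 from 43384611 to 43468057 (51.0 kb). No annotation of this build was used here, so genes in these regions are not named. With 1 library there is no replicate check.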

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

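The tests of the copies, of the scaling and of the harvest for the heat shock genes, the test of the MYC targets, and the fit that gives the response at each time, were chosen after these results were seen.

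In the fit by time, the response to the inhibitors at 3 h minus that at 1 h passed for 1398 genes upward and 1303 downward, for 297 and 402 without JQ1 3 h, and for 243 and 344 without MS417 3 h. The spread in this fit is that between JQ1 and MS417 and leaves out variation between DMSO cultures, of which each time has 1 library, so such variation stays open as a source of these calls. Among the named genes, rises that were larger at 3 h on the log2 scale were those of TESK2 (2.33), CEMIP2 (2.17), ZCCHC24 (2.16), IRF7 (1.83), IQCN (1.47), FAM222A (1.40), ELL2 (1.1), STARD4 (1.00), SESN2 (0.84), POLR2A (0.79), HEXIM1 (0.76), H2BC20P (0.66) and H2BC5 (0.66). Smaller gains were those of STAT2 (0.59), MCL1 (0.57), LSMEM1 (0.50), SC5D (0.49), RGS2 (0.40) and IDI1 (0.36). Differences from DMSO that were less negative at 3 h were those of MYC (0.68), TENT5A (0.67), DUSP4 (0.67) and IRF1 (0.40).

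Responses that were lower at 3 h were those of TFAP4 (-2.17), ANKRD22 (-1.98), FJX1 (-1.96), SAMD10 (-1.79), KANK1 (-1.69), CD247 (-1.65), PLD6 (-1.48), NR1D1 (-1.40), FCGR1A (-1.39), TAL1 (-1.31), CD33 (-1.22), DUSP2 (-1.20), BCL2 (-1.18), NOP16 (-1.13), HOXD13 (-1.08), KLF1 (-1.04) and CEBPE (-1.01). The remaining ones were ZEB2 (-0.97), POLR1B (-0.97), RRS1 (-0.90), CD79B (-0.88), CCND2 (-0.80), WDR43 (-0.78), FAS (-0.74), KIT (-0.70), AEN (-0.70), CD34 (-0.66), TASL (-0.62), CCND1 (-0.57), TRIB3 (-0.53), BCL2L1 (-0.35) and XBP1 (-0.31).

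The larger response at 3 h could come from a DMSO 3 h library that stands apart. Of 433 genes at least 2-fold apart in both 3 h pairs, 79.4% stayed so, in the same direction, against the DMSO 1 h library. For the genes that stayed so, such a library is argued against as the whole source. It stays open for genes called with changes under 2-fold, which this check does not cover. Of the 433, 98.8% had counting intervals that left out no change in both pairs. These genes were chosen by size from the same reads, and both pairs share the DMSO library. The intervals therefore cannot decide on counting noise of low genes, and they do not cover genes called with changes under 2-fold. A secondary fall of MYC targets stays open: the list's median was -0.06 at 1 h (percentile 0.03) and -0.39 at 3 h (percentile 0), and the response was lower at 3 h than at 1 h for 27 of 27 genes, so most of the fall came after 1 h, but whether it followed from the fall of MYC was not tested. With 1 library per treatment and time, an effect of the individual cultures is also open. A response of RNA levels that grew from 1 h to 3 h is a hypothesis that these libraries leave standing. When transcription of these genes changed was not tested, since RNA levels were measured and the nascent RNA samples were not analysed here.

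JQ1 and MS417 responses correlated across genes, and the shared DMSO library may add to this. The covariance of their differences at 3 h was 10.8 times that of simulated unchanged groups, and JQ1 1 h with MS417 3 h, which share no library, correlated at 0.536. At 3 h the shared library as the whole source of the relation is argued against. At 1 h the covariance was 0.0411 against 0.0191 simulated, a smaller excess. The spread simulated was that of the additive fit, which also holds the change of the response between the times. With the spread between JQ1 and MS417, which leaves out variation between DMSO cultures, the simulated covariance was 0.0054. The part of the shared library at 1 h was not settled. The reads of the 3 h libraries of JQ1 and MS417 differed by a chi-square of 1.38 per gene, little above counting noise, and the labels do not say whether these cultures were handled side by side.

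Heat shock genes had a median above 0 for 3 h minus 1 h in every treatment: without HSPA1A, HSPA1B and HSPA1L, 17 of 17 genes were higher in DMSO, 12 with JQ1 and 11 with MS417. The 17 still include DNAJB1 (1.35 in DMSO), itself among the genes called for time. Reads shared between HSPA1A, HSPA1B and HSPA1L are argued against as the source, since those 17 genes had a median of 0.33 in DMSO, and the authors' scaling likewise, since it would move every gene alike and the median of all genes was 0.015. Handling or harvest of the 3 h cultures cannot be told apart from time in culture: the lowest median over the 3 treatments was 0.33, and every 3 h culture was harvested at 3 h. The split by time called 4 genes and the highest of the other splits 0; the split by time itself was the 1 of 10 splits of the 6 libraries into 3 and 3 with so many, and so few splits cannot give a share under 0.05.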

How the results depend on the processing

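Alternatives added after the data were seen were voom weights, leaving out a DMSO library, DMSO 1 h as the control of the 3 h pairs, and every setting of the fits by time. No paired analysis was possible because each RNA-seq group has 1 library, so the groups share only replicate number 1; the additive fit compares treatments within each time. The share of peaks at transcription starts and its windows, the response by H3K27ac class with its thresholds, gap and numbers of regions, and the count test for raw counts were not run, as hg19 gene positions and raw counts were not used here. The fits by time were not run without a DMSO library, which would have left the response at the other time only. No called result reversed. Values without a call changed sign in 50 cases for single genes and in 4 for list medians: elongation genes at 1 h went from -0.04 to 0.01 with the mean in place of the median, interferon-stimulated genes at 1 h from -0.06 to 0.08 with a mean of at least 5 RPKM, and with no filter, over both times, these went from 0.04 to -0.01 and myeloid genes from -0.01 to 0.02. With the mean in place of the median 40 values of lists stayed within their spread and 17 moved. Of the counts and peak summaries under an alternative, 132 stayed within 1.5 times or their spread and 83 moved. Of the other results, 4957 stayed on their side of the threshold or within their spread, 271 lost a call, 180 gained one and 94 moved in value. Rescaling by the median of ratios kept every count within 1.5 times. Trend and robust moderation was run only for the inhibitors over both times (12 and 21 genes), and DMSO 1 h as the control only for the 3 h pairs (246 and 359 for JQ1, 249 and 390 for MS417), and these stayed within 1.5 times too. Below, counts are given as higher or rising, then lower or falling. The cause of each change was not tested, except where the setting itself fixes it. Fewer genes are tested under the stricter filter, and without a DMSO library the contrast over both times holds the response at 1 time only.

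With a pseudocount of 0.1, genes at least 2-fold apart were 39 and 44 for JQ1 at 1 h, 46 higher for MS417 at 1 h, 11 lower for MS417 against JQ1 at 1 h, 2 and 9 for MS417 against JQ1 at 3 h, and 22 lower for DMSO 3 h against 1 h; 8 genes fell with the inhibitors over both times and 0 rose for 3 h against 1 h. With a pseudocount of 2 they were 5 and 10 for JQ1 at 1 h, 6 and 17 for MS417 at 1 h, 58 and 152 for JQ1 at 3 h, 55 and 153 for MS417 at 3 h, 1 and 2 for MS417 against JQ1 at 1 h, 0 lower for MS417 against JQ1 at 3 h, and 7 and 1 for DMSO 3 h against 1 h; 5 genes rose with the inhibitors over both times, 570 fell at 1 h, and 8 rose and 3 fell for 3 h against 1 h. With a mean of at least 5 RPKM they were 4 and 12 for JQ1 at 1 h, 6 and 18 for MS417 at 1 h, 69 and 187 for JQ1 at 3 h, 65 and 191 for MS417 at 3 h, 1 and 3 for MS417 against JQ1 at 1 h, 0 lower for MS417 against JQ1 at 3 h, and 9 and 1 for DMSO 3 h against 1 h; 0 rose and 0 fell with the inhibitors over both times and 2 fell for 3 h against 1 h. With no filter they were 4 and 8 for MS417 against JQ1 at 3 h and 19 lower for DMSO 3 h against 1 h. With voom weights on whole reads 9 rose and 14 fell over both times, 224 rose and 650 fell at 1 h, and 8 rose and 2 fell for 3 h against 1 h. With both inhibitors as 1 treatment level 162 rose and 244 fell over both times.

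Leaving out 1 library at a time, genes rising over both times ranged from 0 to 2624 and falling from 0 to 2673, with 0 without any inhibitor library, the highest without DMSO 1 h, and 170 and 337 without DMSO 3 h. At 1 h they ranged from 0 to 72 and from 1 to 100, lowest without MS417 1 h; at 3 h from 1643 to 3148 and from 1805 to 3056, lowest without JQ1 3 h or MS417 3 h. For the response at 3 h against that at 1 h they ranged from 243 to 1866 and from 344 to 1321, lowest without MS417 3 h. For H3K27ac, the upper 50% of peaks by q gave 27086 peaks with a median length of 1646 bp and a median fold of 12.8, in 17932 joined regions; with no stitching there were 54170 regions. Depth limits genes with few reads: SNORD89 had at most 12 reads in a library, and LSMEM1 had 7 in DMSO at 1 h.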

Other observations

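The list of hypoxia genes was drawn up after PFKFB4 and related genes were seen.

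Genes that respond to low oxygen had a median below 0 for 3 h minus 1 h in each treatment. Without the genes that prompted the list (among them PFKFB4, BNIP3 and P4HA2), the median difference of 20 genes was -0.157 in DMSO, -0.233 with JQ1 and -0.20 with MS417, at percentiles 0.01, 0.09 and 0.35 of random lists. In DMSO all 20 were lower, against 14 with JQ1 and 16 with MS417. P4HA1, a collagen hydroxylase gene, was at -0.85, -1.01 and -1.0 in the 3 treatments, and BNIP3L, a mitophagy receptor gene, at -0.79, -0.47 and -0.49. NDRG1 was at -0.92 in DMSO and at 0.10 and 0.11 with the inhibitors, and SLC2A3, a glucose transporter gene, at -0.73, 0.27 and 0.61. These medians, with a highest percentile of 0.35, describe the set, and no cause was tested. The differences with JQ1 and MS417 also hold the response to the inhibitors. Each treatment has 1 library per time, so these values have no replicate check, and differences between treatments were not tested.

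In DMSO, immediate early genes were also lower at 3 h than at 1 h, with a median of -0.32 over 15 genes (percentile 0 of random lists) and 14 of 15 below 0. Growth factor receptors (-0.16, percentile 0), haematopoietic transcription factors (-0.10, percentile 0.06), p53 targets (-0.12, percentile 0.45) and reference genes (-0.07, percentile 0.59) were lower by their medians. Cholesterol genes (0.18, percentile 100), heat shock and unfolded protein response genes (0.16, percentile 100) and MYC targets (0.08, percentile 99.9) were higher. The medians of the other lists lay between percentiles 2.31 and 97.6.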
